A study of Sus scrofa with 64 samples.

How the data were processed

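The analysis covered the peripheral blood libraries of 64 pigs, 18 at entry, 23 healthy and 23 sick, with the group and the sex of each animal taken from the titles. The deposited values were raw read counts per gene, as the whole numbers and library totals showed. Per the submitters' processing notes, base calls came from CASAVA 1.8, reads were aligned with TopHat2 2.0.2 to the pig genome build Sscrofa10.2 and counted with HTSeq 0.5.3, and globin transcripts had been depleted before library preparation. The strand setting, the annotation release and the counting mode are not given in the sources used here. Each deposited count table listed 25322 Ensembl gene IDs and 5 lines that are not genes. Those lines were kept out of library sizes and tests; as a percent of all reads the tables list, reads outside any gene made up 20.7 ± 3.54%, ambiguous reads 3.98 ± 0.938% and reads with more than 1 alignment 14.6 ± 0.853% (SD, n = 64). Gene symbols were matched to 11804 IDs, of which 8199 were among the 12469 genes tested, and 3 haemoglobin IDs were found. Coordinates were not used here. Total counts over genes ran from 9.24 to 21.6 M reads, and 0 libraries were copies of another.

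All computations from the deposited counts were made in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 with the 3 groups, scaled by TMM factors and tested with the edgeR quasi-likelihood F test with robust dispersion (common dispersion 0.107), which is two-sided. A single fit on all 64 libraries held the group and the sex, and gave sick against healthy, healthy against entry, sick against entry and gilts against barrows. A fit with the interaction of group and sex tested whether the difference between sick and healthy pigs differed between the sexes. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold, and adjusted p below always means this unless another family is named. Genes that differ in sick from both healthy groups passed in the same direction against each. Values per group are CPM with TMM factors, given as mean and SD, and log2 fold changes carry their standard error.

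Gene lists of blood cell types, cytokine families and cell functions were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 25 lists with at least 5 measured genes in each comparison, adjusted over those lists. Camera compares a list with all other genes; fry, which was run beside it, asks whether a list's genes move on balance in a single direction and compares them with no others. The interferon family list had 1 measured gene and was not tested. Some genes belong to more than 1 list, as between the neutrophil, monocyte, pattern recognition, complement and cytokine lists. Results for such lists are therefore not independent of each other. The share of all tested genes that was called was 14.5% in sick against healthy, 6.65% in healthy against entry and 19.7% in sick against entry, which sets the scale for the members called in a list. Shares of counts were compared between groups by two-sided permutation tests of the means with 1e+05 resamples, adjusted over 21 tests. Principal components were computed from log2 CPM, and a library was said to stand apart when it lay over 3 median absolute deviations from the median on components 1 to 4 or in its log2 TMM factor. These were sick 2, sick 16, entry 10 and entry 13.

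The genes named in the text were the up to 8 with a symbol, at least 2 CPM on average and the largest rises or falls among called genes in each comparison; the up to 3 of each list with the smallest p; the 10 with a symbol and the smallest p for a difference of sick pigs from both healthy groups; and the 5 with the smallest p for sex and for the interaction. This rule, the lists, the tests and the alternatives were set before the data were examined, except where the text says that a choice came later. Other settings fixed in this way were DESeq2 1.42.0 and limma voom as tests, DESeq2 size factors (RLE) and library totals as scalings, a looser and a stricter filter, fits without sex or on the compared groups alone, the number in the titles as a block, 2 surrogate variables from sva 3.50.0, the red cell score as a covariate or red cell genes left out, and stricter thresholds.

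The tests were checked on simulated counts with the means, dispersions and library sizes of these samples, in which separate sets of genes were changed by known folds in sick pigs, at entry and in sick gilts. For sick against healthy, edgeR recovered 70.1% of genes changed 1.5-fold, 92.4% of those changed 2-fold and 100% of those changed 4-fold, with 16 false calls. For healthy against entry the shares were 71.6%, 89.6% and 100% with 12 false calls, for sick against entry 69.4%, 91.7% and 100% with 15, and for the sex difference 31.8%, 55.2% and 86.6% with 4. A simulated list of 20 changed genes passed camera (adjusted p = 3.3e-76), and 0 of 20 lists of unchanged genes did. The genes were simulated independently of each other. This check therefore cannot show how often camera with its preset correlation falsely calls a list of correlated genes.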

Results

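Peripheral blood was sampled from 64 commercial pigs with Duroc sires, and reads per gene were counted in the RNA left after globin depletion. The entry group held 18 healthy pigs sampled on arrival at a growing facility, which the study set as its control. The other animals were 23 healthy pigs and 23 sick pigs from the same pens. The titles also name each animal's sex, with 8 barrows (castrated males) and 10 gilts (young females) at entry, 12 barrows and 11 gilts among the healthy pigs, and 12 barrows and 11 gilts among the sick pigs. The disease, its agent, the pigs' ages and the pen of each pig are not given in the sources used here. Each library came from a separate animal, so the errors below measure the spread between pigs. Total counts assigned to genes ranged from 9.24 to 21.6 M reads per library. Their means were 13.9 ± 2.07 M at entry (SD, n = 18), 14.2 ± 2.94 M in healthy pigs (SD, n = 23) and 15.1 ± 3.07 M in sick pigs (SD, n = 23). The first principal component of log2 CPM held 22% of the variance and did not separate the groups (permutation p = 0.253). They differed on component 3, with 9.99% of the variance, and on component 4, with 4.34% (permutation p = 1e-04 for each, the smallest that this test can give).

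The comparison of sick pigs with healthy pen mates asked which blood transcripts mark disease when housing is shared. Sick pigs carried more transcript from genes of neutrophils and of their granules. MMP8 (ENSSSCG00000029675), the collagenase of neutrophil granules, averaged 72 ± 229 CPM in sick pigs (SD, n = 23) against 1.27 ± 1.5 CPM in healthy pigs (SD, n = 23). Its medians were 4.11 CPM in sick and 0.872 CPM in healthy pigs, and 9 of 23 sick pigs lay above the highest healthy one. Its log2 fold change was 5.34 ± 0.69 (SE, edgeR quasi-likelihood adjusted p = 4.5e-07). S100A8, a subunit of the antimicrobial protein calprotectin, rose by 2.97 ± 0.45 (SE, adjusted p = 3.7e-06) and RETN, which encodes resistin, by 2.98 ± 0.45 (SE, adjusted p = 3.8e-06). Without the 4 libraries that stand apart, of which sick 16 reached 1084 CPM of MMP8 and 6780 CPM of S100A8, all 3 kept their calls. The log2 fold changes of MMP8, S100A8 and RETN were then 4.31, 2.12 and 1.93. Monocyte and macrophage genes rose with them, among them CD14 (ENSSSCG00000014369), the co-receptor for bacterial lipopolysaccharide, from 184 ± 68.6 to 543 ± 385 CPM. Of 15 B cell markers 5 fell, among them CD72, an inhibitory co-receptor, by 0.64 ± 0.12 on the log2 scale (SE, adjusted p = 8.7e-05), and the list had adjusted p = 0.077 with an estimated correlation. Across the 12469 genes tested, 1152 were higher and 653 lower in sick pigs at an adjusted p under 0.05, of which 186 and 10 differed by at least 2-fold.

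Of 15 measured neutrophil markers, 10 rose and 0 fell in sick pigs, and 11 rose when the p-values were adjusted over the list alone. ITGAM, a subunit of the adhesion receptor Mac-1, rose by 1.18 ± 0.17 on the log2 scale (SE, adjusted p = 1.6e-06) and lay above the healthy median in 22 of 23 sick pigs. PADI4, an enzyme that converts histone arginine to citrulline, rose by 1.21 ± 0.21 (SE, adjusted p = 3.2e-05). Of 11 measured granule genes of immature neutrophils, 7 rose and 0 fell, with 8 rising and 1 falling when adjusted over the list alone. CHI3L1, a chitinase-like protein among them, went from 307 ± 83.3 to 747 ± 399 CPM (log2 fold change 1.29 ± 0.18, SE, adjusted p = 7.7e-07). Of 21 monocyte and macrophage markers, 12 rose and 0 fell (16 and 0 adjusted over the list alone). MS4A7, a membrane protein of macrophages, rose by 3.63 ± 0.5 and CLEC7A, a receptor for fungal glucan, by 0.99 ± 0.18 (SE, adjusted p = 7.9e-07 and 8.5e-05), the former by 3.02 without the libraries that stand apart. These lists shifted upward against the other genes by camera with its preset correlation (adjusted p = 1.6e-07 for neutrophil markers, 5.8e-07 for granule genes and 3.5e-09 for monocyte markers). The adjusted p values with an estimated correlation were 0.042, 0.034 and 0.031 in the same order.

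**Figure D1:**
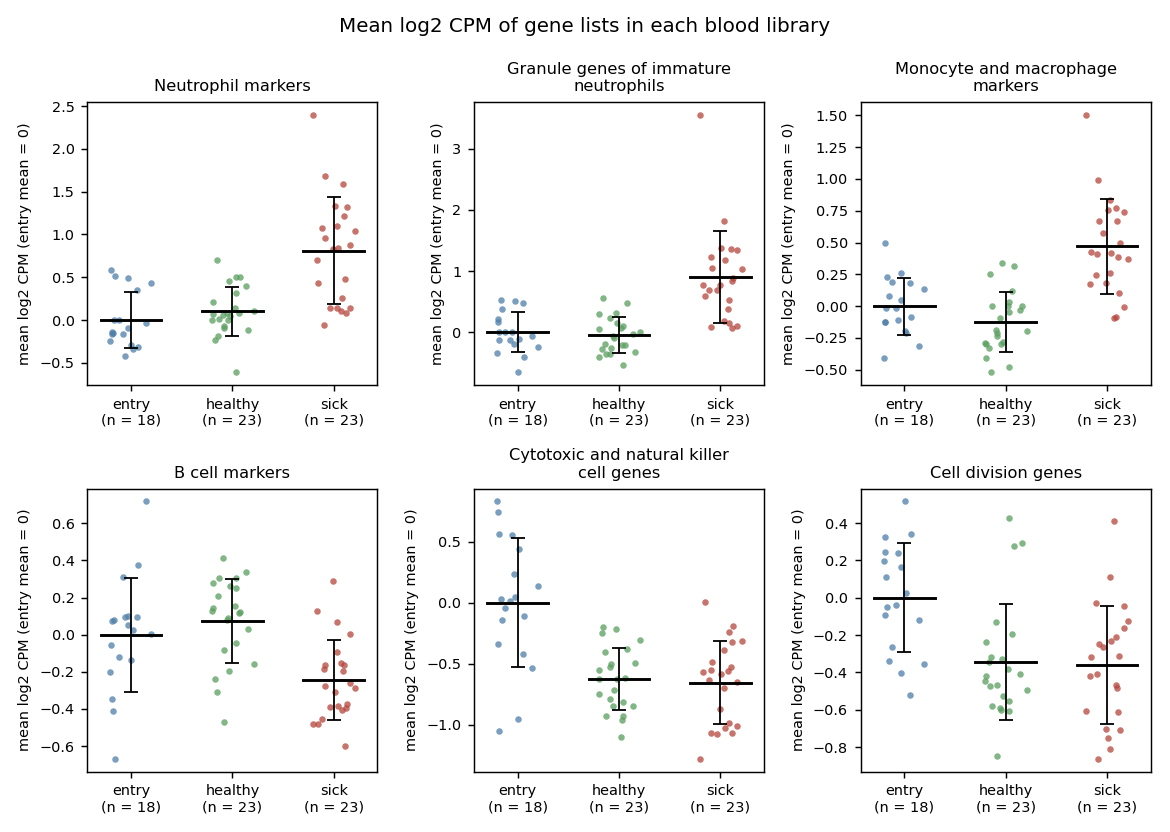
Each point is a blood library, and its height is the mean log2 CPM of the measured genes of a list fixed before the data were examined. Bars give the group mean and whiskers the SD for entry (n = 18), healthy (n = 23) and sick pigs (n = 23). Relative to the entry mean, neutrophil markers averaged 0.1 in healthy and 0.81 in sick pigs, and cytotoxic genes averaged -0.63 and -0.66.

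Of 31 measured pattern recognition and inflammasome genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone), including MYD88, the adaptor of most Toll-like receptors, at 0.64 ± 0.12 on the log2 scale (SE, adjusted p = 7.2e-05). The camera adjusted p was 3.2e-05, and adjusted p = 0.087 with an estimated correlation. Of 10 complement and acute phase genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), led by CFD, a protease of the alternative complement pathway, at 0.65 ± 0.15, and C3AR1, a receptor for a complement fragment, at 1.07 ± 0.26 (SE, adjusted p = 0.0014 and 0.0031). That list had a camera adjusted p of 2.6e-04, and adjusted p = 0.038 with an estimated correlation. Of 23 heat shock and stress genes, 8 rose and 0 fell, and the same counts held when adjusted over the list alone. The 3 leading members, ATF3, IER3 and JUNB, are immediate early genes rather than chaperones and rose by 0.93 ± 0.17, 0.92 ± 0.17 and 0.59 ± 0.12 (SE). The list had a camera adjusted p of 0.011, and adjusted p = 0.19 with an estimated correlation. Of 44 interferon-stimulated genes, 5 rose and 0 fell, with 13 rising when adjusted over the list alone. IRF9, part of the transcription factor that acts below interferon receptors, rose by 0.41 ± 0.1 (SE, adjusted p = 0.0045). Their camera adjusted p was 1.3e-06, and adjusted p = 0.28 with an estimated correlation.

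Of 15 measured B cell markers, 5 fell and 0 rose in sick pigs (6 and 0 adjusted over the list alone). SWAP70, a signalling protein of activated B cells, changed by -0.40 ± 0.082 on the log2 scale (SE, adjusted p = 4.6e-04). The camera adjusted p was 3.5e-06, and adjusted p = 0.077 with an estimated correlation. Of 9 genes of MHC class II presentation, 3 fell and 0 rose, namely SLA-DOA, SLA-DQB1 and SLA-DMB at -0.40 ± 0.12, -0.38 ± 0.11 and -0.31 ± 0.11 (SE, adjusted p = 0.014, 0.016 and 0.04). Adjusted over the list alone 2 rose and 6 fell, and the list did not pass (camera adjusted p = 0.059). Without the libraries that stand apart SLA-DMB was at -0.28, about as large a change but not called (adjusted p = 0.061). Counts of SLA genes are uncertain because their sequences are alike. Of 27 T cell markers, 3 fell and 0 rose (1 and 0 adjusted over the list alone), with CD247, a signalling chain of the T cell receptor, at -0.30 ± 0.081 (SE, adjusted p = 0.0069), and the list did not pass (camera adjusted p = 0.066). CD8B and LEF1, the other called T cell markers, were not called without entry 8, healthy 5 and healthy 22, which are treated below (-0.31 and -0.23, edgeR adjusted p = 0.12 for each). They were also not called without the libraries that stand apart (-0.38 and -0.25, edgeR adjusted p = 0.063 and 0.1). Of 11 plasma cell genes, 3 rose and 0 fell, with 5 rising when adjusted over the list alone. ELL2, an elongation factor used in antibody secretion, rose by 0.61 ± 0.11 (SE, adjusted p = 5.8e-05), and for the list the camera adjusted p was 0.016, and adjusted p = 0.23 with an estimated correlation. PRDM1 and SDC1, the other called plasma cell genes, were not called without entry 8, healthy 5 and healthy 22 (0.35 and 0.41, edgeR adjusted p = 0.051 and 0.065). Of 13 platelet genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone), namely P2RY12, the receptor for ADP on platelets, and F13A1, a clotting transglutaminase, at 0.65 ± 0.2 and 0.57 ± 0.19 (SE), both not called with library totals in place of TMM factors (0.56 for each, adjusted p = 0.064 and 0.075). For platelet genes the camera adjusted p was 0.019, and adjusted p = 0.23 with an estimated correlation.

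The cytokine families are named in the title of the study, so these lists are not independent evidence of their direction. Of 89 measured cytokine and cytokine receptor genes, 30 rose and 2 fell in sick pigs, with 31 and 3 when adjusted over the list alone (camera adjusted p = 2.3e-06, and adjusted p = 0.031 with an estimated correlation). ACVR1B (ENSSSCG00000000233), an activin receptor, went from 5.79 ± 2.62 to 31.9 ± 37.4 CPM, a log2 fold change of 2.38 ± 0.29 (SE, adjusted p = 1.4e-07). IL22RA2 (ENSSSCG00000004158), a soluble receptor that binds interleukin 22, went from 4.86 ± 4.72 to 60.1 ± 63.5 CPM (log2 fold change 3.63 ± 0.5, SE, adjusted p = 7.7e-07) and lay above the healthy median in 15 of 23 sick pigs. Among interleukins and receptors, 11 of 34 rose and 1 fell (12 and 1 adjusted over the list alone), including IL4R at 0.92 ± 0.13 (SE). Interleukins had a camera adjusted p of 0.0012, and adjusted p = 0.073 with an estimated correlation. Among the TNF superfamily, 8 of 16 rose and 1 fell, with the same counts when adjusted over the list alone, including RELT, TNFRSF21 and TNFRSF1B at 1.04 ± 0.16, 1.09 ± 0.18 and 0.78 ± 0.13 (SE). TNF superfamily genes had a camera adjusted p of 6.4e-04, and adjusted p = 0.042 with an estimated correlation. Among colony stimulating factors and receptors, 3 of 7 rose and 0 fell, with the same counts when adjusted over the list alone, namely CSF2RB, CSF3R and CSF1R at 0.80 ± 0.15, 1.37 ± 0.29 and 0.70 ± 0.2 (SE). This list had a camera adjusted p of 0.019, and adjusted p = 0.11 with an estimated correlation. CSF3R is also a member of the neutrophil marker list, and CSF1R of the monocyte marker list. Chemokines and receptors (3 of 17 rose, 0 fell) and the TGF-beta and activin family (4 of 14 rose, 0 fell) kept these counts when adjusted over the list alone and did not pass as lists (camera adjusted p = 0.077 for each). The chemokine receptor CCR1 rose by 1.05 ± 0.17, and IFNGR1, the only measured member of the interferon family list, by 1.02 ± 0.16 (SE).

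**Figure D2:**
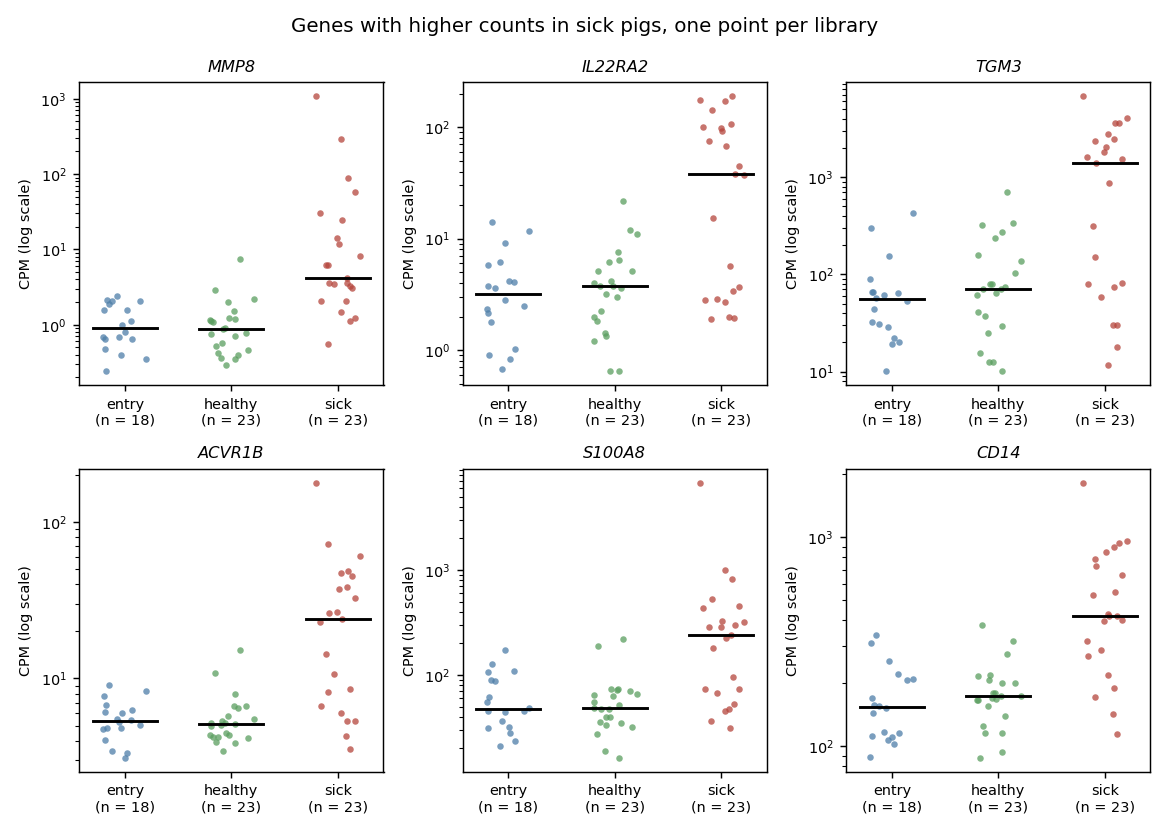
Each point is the CPM of a gene in a blood library on a log axis, with bars at the group median, for entry (n = 18), healthy (n = 23) and sick pigs (n = 23). Sick libraries reached 1084 CPM for MMP8 and 6810 CPM for TGM3, while the healthy libraries stayed at or under 7.47 and 699 CPM.

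Cell division (0 of 35 called), ribosomal protein (0 of 23) and oxidative phosphorylation genes (0 of 40) held no called gene in sick against healthy pigs by edgeR, and none when adjusted over the list alone. With library totals in place of TMM factors, 6 ribosomal protein and 3 oxidative phosphorylation genes were called lower. As a list, ribosomal protein genes lay lower by camera (adjusted p = 0.0094), and adjusted p = 0.58 with an estimated correlation. Cytotoxic, erythroid, eosinophil and dendritic cell lists did not pass (camera adjusted p = 0.77, 0.27, 0.85 and 0.29), and the median, the mean and the test of the first 3 of these lists differed in sign. Their called members, out of 18, 35, 12 and 7 measured, were 3, 2, 2 and 2 genes. FCER1G and TYROBP, adaptors also used by monocytes, rose by 0.85 ± 0.14 and 0.70 ± 0.14, and OLIG2, a transcription factor, by 1.61 ± 0.28 (SE, adjusted p = 3.2e-05). Among the largest changes outside the lists, TGM3, a transglutaminase best known from skin, went from 128 ± 158 to 1559 ± 1756 CPM (log2 fold change 3.60 ± 0.58, SE, adjusted p = 1.2e-05). KCNJ15, a potassium channel subunit that belongs to the neutrophil marker list, rose by 3.44 ± 0.61 (SE, adjusted p = 5.5e-05). Outside the lists, CHIT1, a chitinase of activated macrophages, rose by 2.88 ± 0.42 (SE, adjusted p = 1.8e-06), or by 2.19 without the libraries that stand apart. CD1E, a lipid antigen protein, DNTT, the terminal transferase of developing lymphocytes, and MYB, a regulator of blood progenitors, changed by -3.21 ± 0.73, -2.17 ± 0.63 and -1.02 ± 0.32 (SE, adjusted p = 0.0014, 0.013 and 0.021). Those 3 calls were lost without entry 8, healthy 5 and healthy 22, where the values were -0.31, 0 and -0.26 (adjusted p = 0.52, 1 and 0.13). Of these libraries, entry 8 is in neither group compared and can act only through the shared fit. The next largest falls were in ELOVL3, a fatty acid elongase, and NTN4, a netrin, at -0.89 ± 0.26 and -0.82 ± 0.21 (SE, adjusted p = 0.013 and 0.0039).

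Red cell genes took 3.58 ± 2.89% of the counts in sick and 4.64 ± 2.72% in healthy pigs (permutation p = 0.21, two-sided). Scaling matters for the balance of directions, since 773 genes were higher and 700 lower with library totals in place of TMM factors, and the median of the erythroid list changed sign. With those totals, the genes called higher went from 5 to 2 among interferon-stimulated genes, from 3 to 1 among plasma cell genes, from 2 to 0 among platelet genes and from 4 to 1 in the TGF-beta and activin family. Heat shock and stress genes had 7 higher and 2 lower in place of 8 and 0.

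The comparison of healthy pen mates with entry pigs asked what differed between healthy animals sampled at arrival and later. Healthy pen mates carried less transcript from 13 of 18 cytotoxic and natural killer cell genes, whose list had adjusted p = 0.075 with an estimated correlation. GZMH, a granule protease of killer cells, averaged 200 ± 157 CPM at entry (SD, n = 18) and 54.3 ± 36.6 CPM in healthy pen mates (SD, n = 23), a log2 fold change of -1.88 ± 0.29 (SE, edgeR adjusted p = 3.2e-05). CCL5, a chemokine released by activated T and natural killer cells, fell by 1.53 ± 0.24 (SE, adjusted p = 3.2e-05) and lay below the entry median in 23 of 23 pen mates. Of 35 cell division genes 13 fell, or 1 with library totals in place of TMM factors, and the list had adjusted p = 0.27 with an estimated correlation. GATA2, a transcription factor of basophils, mast cells and progenitors, rose from 7.59 ± 2.58 to 16.9 ± 9.93 CPM (log2 fold change 1.15 ± 0.28, SE, adjusted p = 0.0083). In all, 444 genes were higher and 385 lower in healthy pen mates, of which 21 and 79 differed by at least 2-fold.

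Of 18 measured cytotoxic and natural killer cell genes, 13 fell and 1 rose, with the same counts when adjusted over the list alone, and IL2RB, a receptor chain for interleukins 2 and 15, changed by -0.83 ± 0.14 (SE, adjusted p = 8.8e-05). The camera adjusted p was 1.8e-10, and adjusted p = 0.075 with an estimated correlation. Of 35 cell division genes, 13 fell and 0 rose (24 and 0 adjusted over the list alone). The replicative helicase subunits MCM5, MCM2 and MCM4 changed by -0.50 ± 0.1, -0.45 ± 0.11 and -0.40 ± 0.096 (SE, adjusted p = 0.0016, 0.0066 and 0.0066), of which MCM2 and MCM4 were not called with library totals in place of TMM factors (-0.36 and -0.32, adjusted p = 0.054 and 0.099). With those totals 1 cell division gene was called lower in place of 13. Cell division genes had a camera adjusted p of 1.5e-14, and adjusted p = 0.27 with an estimated correlation. Of 44 interferon-stimulated genes, 3 fell and 0 rose, namely GBP2, TRIM25 and UBE2L6 at -0.84 ± 0.15, -1.11 ± 0.27 and -0.62 ± 0.18 (SE), and 19 fell when adjusted over the list alone. Interferon-stimulated genes had a camera adjusted p of 9.5e-11, and adjusted p = 0.39 with an estimated correlation. Of 35 erythroid genes, 2 fell and 0 rose, with 4 falling when adjusted over the list alone (camera adjusted p = 5.6e-04, and adjusted p = 0.79 with an estimated correlation). These were the catalase gene CAT and the erythroid factor KLF1, at -0.39 ± 0.11 and -1.04 ± 0.33 (SE), and neither was called without the libraries that stand apart (-0.33 and -0.86, adjusted p = 0.064 and 0.093). Of 40 oxidative phosphorylation genes 1 fell, COX8A at -0.58 ± 0.18 (SE), or -0.57 with adjusted p = 0.052 without entry 8, healthy 5 and healthy 22, and 0 when adjusted over the list alone. The oxidative phosphorylation list had a camera adjusted p of 0.0042, and adjusted p = 0.79 with an estimated correlation.

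Among cytokine families in healthy pen mates, the TGF-beta and activin list rose, with 4 of 14 members higher, 0 lower and the same counts when adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.075 with an estimated correlation). ACVR2A, an activin receptor, rose by 1.15 ± 0.22 (SE, adjusted p = 7e-04), while BMPR2 and TGFBR1 rose by 0.25 ± 0.074 and 0.30 ± 0.096 (SE), the former at 0.22 with adjusted p = 0.058 without the libraries that stand apart. All 4 called chemokine genes fell, including CCL3L1, a macrophage inflammatory protein, at -1.47 ± 0.23 (SE). The list of 17 did not pass (camera adjusted p = 0.11), and its counts were the same when adjusted over the list alone. Interleukins (3 rose and 4 fell of 34), the TNF superfamily (1 rose and 1 fell of 16) and colony stimulating factors (0 called of 7) also kept their counts when adjusted over the list alone and did not pass (camera adjusted p = 0.21, 0.64 and 0.64). IL12RB1, a receptor chain for interleukin 12, changed by -0.47 ± 0.082 and FASLG, a death ligand of killer cells, by -1 ± 0.18 (SE). CCL3L1 has near-identical copies in mammals, so its count is uncertain. Over all 89 cytokine and receptor genes 8 rose and 9 fell (9 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.27). The title of the study names these families, so the counts are not independent evidence. Neutrophil markers (1 higher and 1 lower of 15), granule genes (0 of 11 called) and monocyte markers (1 higher and 2 lower of 21) did not pass as lists (camera adjusted p = 0.27, 0.92 and 0.64). CX3CR1, the fractalkine receptor, fell by 1.27 ± 0.26, and MMP9, a gelatinase stored in neutrophils, rose by 1.09 ± 0.26 (SE, adjusted p = 0.0012 and 0.0074). Between sick and healthy pigs MMP9 was not among the neutrophil markers that rose, at -0.31 ± 0.24 (SE, adjusted p = 0.41). T cell markers (3 higher and 2 lower of 27) and B cell markers (1 higher and 1 lower of 15) did not pass either (camera adjusted p = 0.76 and 0.27). GATA3, LEF1 and BLK, a B cell kinase, rose by 0.55 ± 0.14, 0.41 ± 0.11 and 0.61 ± 0.14 (SE). The median, the mean and the test differed in sign for T cell markers, pattern recognition genes (0 of 31 called) and dendritic cell genes (0 of 7 called), none of which passed. Plasma cell, platelet, eosinophil and basophil, MHC class II, complement, ribosomal protein and heat shock lists did not pass either (camera adjusted p = 0.41, 0.27, 0.27, 0.34, 0.6, 0.64 and 0.22).

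The largest falls between entry pigs and healthy pen mates were in genes of connective tissue. COL3A1 and COL1A2, which encode fibrillar collagens, averaged 115 ± 217 and 38 ± 60 CPM at entry against 10.6 ± 12.1 and 3.68 ± 3.58 CPM in healthy pen mates (log2 fold changes -3.37 ± 0.86 and -3.32 ± 0.76, SE, adjusted p = 0.011 and 0.0044). POSTN, DCN, CLEC3B and COL5A1, all genes of the extracellular matrix, changed by -2.71 ± 0.68, -2.59 ± 0.78, -1.89 ± 0.47 and -1.64 ± 0.36 (SE). Entry libraries differed widely from each other, with COL3A1 between 0.564 and 900 CPM. Red cell genes took 6.4 ± 3.2% of counts at entry and 4.64 ± 2.72% in healthy pen mates (permutation p = 0.064, two-sided), which bears on the erythroid list. The split of directions was 712 higher and 153 lower with library totals in place of TMM factors. The median log2 fold change of all genes moved from -0.02 to 0.05. With those totals the medians of the chemokine, T cell, plasma cell, MHC class II and ribosomal protein lists, none of which passed, changed sign, and T cell markers had 2 higher and 0 lower in place of 3 and 2.

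**Figure D3:**
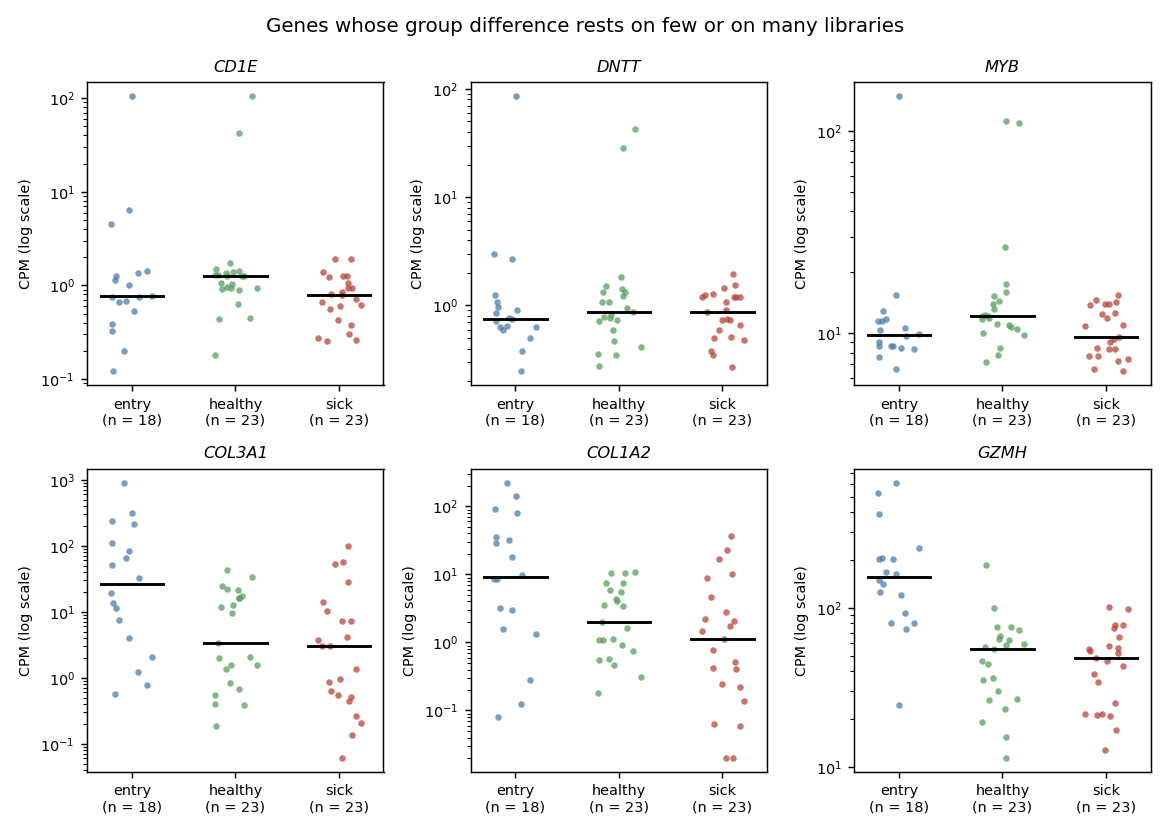
Each point is the CPM of a gene in a blood library on a log axis, with bars at the group median, for entry (n = 18), healthy (n = 23) and sick pigs (n = 23). CD1E and DNTT stood high in 3 libraries, COL3A1 and COL1A2 spread widely within the entry group, and GZMH was lower in 22 of 23 healthy pigs than the entry median.

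The comparison of sick pigs with the entry group set disease against the study's control and so carries disease, age and time in the facility together. Higher in sick pigs were 7 of 11 granule genes and 12 of 21 monocyte markers, and lower were 14 of 18 cytotoxic and 20 of 35 cell division genes. Their adjusted p values with an estimated correlation were 0.066, 0.068, 0.068 and 0.13. MMP8 rose by 5.14 ± 0.79 on the log2 scale (SE, edgeR adjusted p = 2.2e-06), or by 4.20 without the libraries that stand apart. SERPINB1, an inhibitor of neutrophil proteases, went from 203 ± 36.3 CPM at entry (SD, n = 18) to 455 ± 399 CPM in sick pigs (SD, n = 23), above the entry median in 23 of 23. TGFBI, a matrix protein made by monocytes, rose by 1.28 ± 0.18 (SE, adjusted p = 4.2e-07). TBX21 and GZMA, the T-bet factor and a granule protease of killer cells, changed by -1.28 ± 0.17 and -1.53 ± 0.21 (SE, adjusted p = 2.2e-07 and 4.5e-07), each below the entry median in 23 of 23 sick pigs. TGM3 and IL22RA2 rose by 4.03 ± 0.66 and 3.76 ± 0.56 (SE). By edgeR, 1404 genes were higher and 1055 lower, of which 251 and 79 differed by at least 2-fold. The split was 1284 and 487 with library totals in place of TMM factors. With those totals 3 B cell markers were lower in place of 5, 3 complement genes higher in place of 5, 3 ribosomal protein genes lower in place of 1, 2 T cell markers lower in place of 4 and 0 heat shock genes lower in place of 2.

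In sick against entry pigs 12 of 15 neutrophil markers rose and 0 fell (13 and 1 adjusted over the list alone), including NCF1, a subunit of the phagocyte oxidase, at 1.14 ± 0.17 (SE). Neutrophil markers had a camera adjusted p of 4.6e-08, and adjusted p = 0.04 with an estimated correlation. Granule genes (7 of 11 rose, 0 fell, the same adjusted over the list alone) and monocyte markers (12 of 21 rose, 2 fell, the same adjusted over the list alone) had camera adjusted p of 3e-05 and 9e-06, and adjusted p = 0.066 and 0.068 with an estimated correlation. Cytotoxic genes (14 of 18 fell, 2 rose, the same adjusted over the list alone) and cell division genes (20 of 35 fell, 0 rose, 27 and 0 adjusted over the list alone, 7 and 0 with library totals) had camera adjusted p of 4.8e-07 and 1.8e-10, and adjusted p = 0.068 and 0.13 with an estimated correlation. The cytokine and receptor list, not independent of the study's title, held 34 genes that rose and 9 that fell of 89 (37 and 10 adjusted over the list alone). RELT and TNFSF13B, the B cell factor BAFF, each rose by 1.29 ± 0.18 (SE). All cytokine and receptor genes together had a camera adjusted p of 1.3e-06, and adjusted p = 0.023 with an estimated correlation. Within it the interleukins (15 rose and 3 fell of 34, 16 and 6 adjusted over the list alone) and the TGF-beta family (4 rose and 0 fell of 14, 6 and 0 adjusted over the list alone) kept their calls with an estimated correlation (adjusted p = 0.04 and 0.0053). The TNF superfamily (7 rose and 2 fell of 16) and the colony stimulating list (4 rose and 0 fell of 7) kept their counts when adjusted over the list alone. They had camera adjusted p of 0.0011 and 0.013, and adjusted p = 0.066 and 0.11 with an estimated correlation. Chemokines (3 rose and 4 fell of 17) did not pass (camera adjusted p = 0.82).

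In sick against entry pigs, pattern recognition genes (11 of 31 rose, 0 fell), complement genes (5 of 10 rose, 0 fell) and platelet genes (4 of 13 rose, 0 fell) kept these counts when adjusted over the list alone and had camera adjusted p of 2.5e-04, 0.014 and 0.0028, and adjusted p = 0.13 for each with an estimated correlation. NLRP3, an inflammasome sensor, rose by 0.92 ± 0.15, and THBS1, an adhesive glycoprotein of platelets and monocytes, by 0.93 ± 0.21 (SE). B cell markers (5 of 15 fell, 0 rose, 8 and 0 adjusted over the list alone) and MHC class II genes (3 of 9 fell, 1 rose, 6 and 1 adjusted over the list alone) had camera adjusted p of 0.004 and 0.0094, and adjusted p = 0.26 and 0.19 with an estimated correlation. RFX5, a transcription factor of class II genes, changed by -0.36 ± 0.07 (SE, adjusted p = 8.8e-05). Erythroid genes (6 of 35 fell, 1 rose, the same adjusted over the list alone) had a camera adjusted p of 1.5e-04, and adjusted p = 0.36 with an estimated correlation. ALAS2, the erythroid enzyme of haem synthesis, changed by -1 ± 0.35 (SE, adjusted p = 0.033). The share of counts from red cell genes was 3.58 ± 2.89% in sick and 6.4 ± 3.2% in entry pigs (permutation p = 0.0052, adjusted p = 0.028 over 21 tests). Ribosomal protein genes (1 of 23 fell, RPLP1, at -0.42, or -0.35 with adjusted p = 0.072 without the libraries that stand apart, and 0 adjusted over the list alone) and oxidative phosphorylation genes (5 of 40 fell, 1 rose, 4 and 1 adjusted over the list alone) had camera adjusted p of 0.0066 and 1.9e-04, and adjusted p = 0.55 and 0.46 with an estimated correlation. T cell, plasma cell, interferon-stimulated, eosinophil, dendritic and heat shock lists did not pass (camera adjusted p = 0.21, 0.21, 0.32, 0.2, 0.21 and 0.38). GBP2, an interferon-induced GTPase, changed by -1.05 ± 0.15, LCK, a T cell kinase, by -0.55 ± 0.093 and DUSP1, a stress-induced phosphatase, by 0.94 ± 0.14 (SE). The median of the heat shock list was below 0 while its mean and test were above. POSTN, COL3A1, COL1A2 and CLEC3B were again lower than at entry, by -3.38 ± 0.66, -3.09 ± 0.84, -2.89 ± 0.75 and -2.53 ± 0.49 (SE). CD1E, DNTT and COL5A2 changed by -2.91 ± 0.79, -2.39 ± 0.7 and -1.85 ± 0.6 (SE), and by -0.60, -0.11 and -0.73 without entry 8, healthy 5 and healthy 22, where none of the 3 was called (adjusted p = 0.16, 0.79 and 0.089).

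Genes that set sick pigs apart from both healthy groups were mostly higher ones. The change passed in the same direction against healthy and against entry pigs for 1017 genes, 833 higher and 184 lower, and 989 of them did not differ between the 2 healthy groups at the threshold. The genes with the smallest p were ACVR1B, CHI3L1, CD14, ADGRG3, a receptor of granulocytes, CERS4, a ceramide synthase, IL22RA2, SMPDL3B, a phosphodiesterase of lipid membranes, NETO2, MS4A7 and MMP8. All of these were higher in sick pigs, and between healthy and entry pigs their log2 differences ran from -0.20 for MMP8 to 0.46 for SMPDL3B, none called. ADGRG3 went from 24.3 ± 10.9 CPM at entry (SD, n = 18) and 29.3 ± 11.5 CPM in healthy pigs (SD, n = 23) to 85.7 ± 64.8 CPM in sick pigs (SD, n = 23). Both tests use the same sick libraries, which alone makes their results alike. In 20 simulations of unchanged groups the log2 fold changes correlated at 0.466 on average, against 0.675 here. The covariance was 0.0133 against 0.0865, and 0 simulated genes were called in both. Each gene was simulated independently, so variation that moves many genes together is missing. The simulated values therefore do not measure how many shared genes chance could give in real blood. Independent lists of these lengths would share 130 higher and 55 lower genes. With 11 sick libraries set against healthy pigs and the other 12 against entry pigs, 515 genes passed in both, and 234 with the sets exchanged, at covariances of 0.0601 and 0.0734.

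Gilts and barrows were compared over all groups. Of 27 genes called, 14 were higher and 13 lower in gilts, and the strongest had no symbol. The count depends on the setting, with 148 by DESeq2, 114 by limma voom and 374 without the libraries that stand apart. ENSSSCG00000026430 had at least 155 CPM in every barrow and at most 0.475 CPM in every gilt (log2 difference -11.17). For ENSSSCG00000012178 the bounds were 273 and 1.44 CPM (log2 difference -10.77), so the sexes in the titles fit the counts of all 64 libraries. Whether the response to sickness differed between the sexes was tested as an interaction, and 0 of 12469 genes passed by edgeR, with 647 at an unadjusted p under 0.05. DESeq2 also gave 0 with 726 at an unadjusted p under 0.05, and limma voom 0 with 582. The smallest interaction p values with a symbol belonged to SLC39A7, a zinc transporter, DZIP3 and NFKBIL1, at -0.47 ± 0.13, 1.21 ± 0.34 and -0.58 ± 0.17 on the log2 scale (SE, adjusted p = 0.81 for each). On simulated counts of this design, 86.6% of 4-fold, 55.2% of 2-fold and 31.8% of 1.5-fold sex differences were recovered by edgeR, so the test had limited power for differences of 2-fold and less.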

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

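In this part, the tests of the calls without entry 8, healthy 5 and healthy 22, of the depth of these libraries and of the number of entry pigs with high COL3A1 were chosen only after the results were seen, as were the fit of the sex difference without sick 16 and the demand that the granule score pass its limit by more than its error. The difference between sick and healthy pigs in 5 lists was itself different between the sexes by camera with its preset correlation. The score of granule genes of immature neutrophils rose by 1.18 in barrows and 0.69 in gilts (adjusted p = 0.0061, n = 12 and 11 sick pigs). Cell division genes moved by -0.11 in barrows and 0.09 in gilts (camera adjusted p = 0.0036), ribosomal protein genes by -0.05 and -0.23 (adjusted p = 0.0056), oxidative phosphorylation genes by 0.04 and -0.15 (adjusted p = 2.9e-05), and heat shock and stress genes by 0.26 and 0.11 (adjusted p = 0.043). Without sick 16, which stands apart, the granule score rose by 0.95 in barrows and 0.69 in gilts, and neither that list nor heat shock genes passed (camera adjusted p = 0.095 and 0.2), while cell division, ribosomal protein and oxidative phosphorylation genes did (adjusted p = 0.0091, 0.0091 and 9.5e-05). With an estimated correlation and all libraries the adjusted p was 0.97 for each of these lists, and no single gene passed the interaction by edgeR, with 647 at an unadjusted p under 0.05, by DESeq2 with 726, or by limma voom with 582.

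Some of the reads outside the gene counts also differed, but reads outside any gene did not (20.3% in sick and 20.7% in entry pigs, permutation p = 0.76). The share of red cell genes differed between sick and entry pigs too (permutation p = 0.0052). Whether the differences below follow that share was not tested. Reads that overlap more than 1 gene made up 3.46% in sick and 4.61% in entry pigs, a difference of -1.15 points (permutation p = 0.00023, adjusted p = 0.0024 over 21 tests). Reads with more than 1 alignment made up 15.1% in sick and 14% in entry pigs, a difference of 1.1 points (permutation p = 2e-05, adjusted p = 0.00042).

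CD1E, DNTT and MYB were lower in sick than in healthy pigs, but without entry 8, healthy 5 and healthy 22 the test called 0 of these 3 genes. The calls thus rest on these libraries, of which entry 8 is in neither group compared. All 3 libraries were left out because of their high values, so this cannot decide whether smaller differences remain. The medians in healthy and sick pigs were 1.25 and 0.791 CPM for CD1E, 12.2 and 9.56 CPM for MYB, and 0.865 and 0.864 CPM for DNTT. CD1E reached at least 42.7 CPM in these libraries and at most 6.42 CPM in the other 61, and RAG1, a recombinase of developing lymphocytes, at least 10.1 and at most 1 CPM. Total counts argue against depth, since 0 of the 3 libraries lay outside the range of the others. RNA of immature T cells of the thymus is a candidate source that stays open: ARPP21, at 14.6 CPM or more against at most 0.902 CPM, was the 1 gene of 8 not examined earlier whose 3 highest libraries were these, beside 8 of 8 genes examined earlier. Of the other 7, CD1B, TOX, TESPA1, GFI1 and CCR9 have medians of 173, 42.8, 19.9, 14.7 and 7.06 CPM in the other libraries, where a small share of such cells might not show. SMPD3 and TOX2, with medians of 3.05 and 0.187 CPM, were at 2.88 and 0.0992 CPM in the lowest of the 3 libraries and give this source no support. They cannot exclude it, since each value is from 1 library and TOX2 was low throughout (at most 0.919 CPM in the other 61).

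COL3A1, COL1A2, DCN and POSTN were higher at entry than in healthy pen mates. In COL3A1, 8 of 18 entry libraries and 3 of 23 sick libraries lay above the highest healthy library. Within the entry libraries, 10 connective tissue genes not examined earlier followed these 4 genes (Pearson r = 0.77, permutation p = 2e-04, adjusted p = 0.0012 over 6 relations; Spearman rho = 0.68, permutation p = 0.002, adjusted p = 0.012), with r = 0.69 without the 2 farthest libraries, so connective tissue in some samples is a candidate cause. Skin epithelium genes, 4 of which had enough reads for a score but only 2 for the gene tests, followed them as well (r = 0.58, permutation p = 0.012, adjusted p = 0.036; rho = 0.55, permutation p = 0.02, adjusted p = 0.04; r = 0.56 without the 2 farthest), whereas rho was 0.49 for muscle, -0.10 for endothelium and -0.13 for fat (adjusted p = 0.06, 0.69 and 0.69). For thymocyte genes rho was 0.59 (adjusted p = 0.033) and r was 0.38 (adjusted p = 0.16), so that relation did not hold by both measures. Age, place and handling at entry are the group itself and cannot be told apart from this source.

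Neutrophil markers were higher in sick than in healthy pigs, and the tables argue against 2 explanations as the whole cause. Without the libraries that stand apart 9 of 15 markers were still called higher, and with the red cell score in the design 11 were. The score of granule genes of immature cells minus that of neutrophil markers was 0.24 ± 0.1 higher in sick pigs (SE, two-sided permutation p = 0.026), and 0.21 without sick 2 and sick 16, which passes the limit of 0.2 written before the result and so counts against a higher share of neutrophils of unchanged make-up, but by less than its error. With that error taken into account, which was done after the value was seen, such a share stays open. More immature neutrophils may therefore add to a higher share, and cell counts, which would decide it, are not given in the sources used here.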

How the results depend on the processing

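The tests without the libraries that stand apart (sick 2, sick 16, entry 10 and entry 13) and without entry 8, healthy 5 and healthy 22, and that of the sex difference of lists without sick 16, were chosen after seeing the data. Counts of called genes for the 3 group comparisons and for genes that differ in sick from both healthy groups stayed within 1.5 times of the reported ones with DESeq2, limma voom, other scalings and filters, fits without sex or on fewer libraries, and red cell corrections. Stable counts did not always mean the same genes. The reported counts were 1805 for sick against healthy, 829 for healthy against entry, 2459 for sick against entry and 1017 for both. With library totals 1213, 543, 1657 and 702 of these genes were called in that order, and with DESeq2 1799, 827, 2455 and 1014. With 2 surrogate variables the counts were 3041 for sick against healthy, 1959 for healthy against entry, 3942 for sick against entry and 1674 for both, and the cause was not tested. By construction they fell to 851, 243, 1361 and 560 at an adjusted p under 0.01, and to 590, 260, 868 and 420 with at least a 1.5-fold difference. The number in the titles was not shown to pair the pigs. Libraries of healthy and sick pigs with the same number correlated at 0.046 on average, against -0.002 for other numbers, and were over 0.1 in 9 of 23 pairs. Of the sick libraries 2 correlated best with their own number, and 7 of 23 pairs were of the same sex. Pen mates need not be alike in sex or in expression, so these values cannot exclude a pairing. With this number as a replicate block, 520 genes were called in healthy against entry, 1376 in sick against entry and 645 in both, while sick against healthy gave 1526; the block also uses fewer libraries. Gilts against barrows gave 148 genes with DESeq2, 114 with limma voom, 49 with surrogate variables, 43 with the red cell score, 374 without the libraries that stand apart, 93 without entry 8, healthy 5 and healthy 22, and 16 with at least a 1.5-fold difference, for causes that were not tested. The sex difference in sick against healthy pigs gave 1 gene with no filter on low counts and 0 by edgeR in the other settings. Without sick 16 the gilt minus barrow gap in the score difference moved from -0.01 to 0.03 for colony stimulating genes and from 0 to 0.08 for monocyte and 0.05 for pattern recognition genes, none of which passed either way. With an estimated correlation 6 of 15 lists kept their call in sick against healthy, 0 of 6 in healthy against entry and 4 of 18 in sick against entry. Fry called 17, 5 and 18 lists in that order, among them 14 of those 15, 4 of those 6 and 16 of those 18. By fry alone, chemokines, the TGF-beta family and MHC class II genes passed in sick against healthy pigs (fry adjusted p = 0.0094, 9e-04 and 0.031). Chemokines did so in healthy against entry pigs (fry adjusted p = 0.02), and eosinophil and dendritic lists in sick against entry pigs (fry adjusted p = 0.017 and 0.025). The difference in the share of the 10 most abundant genes between healthy and entry pigs was -2.41 points (permutation p = 0.033, adjusted p = 0.077 over 21 tests), which like that of red cell genes did not pass, and the difference in haemoglobin genes alone between sick and entry pigs was -1.24 points, not past it. The log2 fold change of DNTT between sick and healthy pigs was 0.01 with DESeq2, which replaces outlying counts, and 0 without entry 8, healthy 5 and healthy 22. Of the other values for named genes, 3663 kept direction and side of the threshold, 65 passed it and 292 fell short of it; of those for lists, 407 kept both, 8 passed and 35 fell short. The planned fit without libraries of low total count was not run, because the smallest total, 9.24 M reads, was above its limit beside a median of 14.6 M. On simulated counts of this depth, 70.1% of 1.5-fold changes between sick and healthy pigs were recovered, which limits what the lists can show about smaller ones.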

Other observations

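The lists of this part, the spread of the neutrophil score, the fit with that score and the comparison of barrows with gilts were chosen only after other results were seen. The list of matrix metalloproteases and transglutaminases was made after MMP8 and TGM3 had been seen to rise and holds both. Only its 9 measured genes that had neither been looked at, nor been named, nor belonged to an earlier list were therefore tested. They were MMP2, MMP19, TGM1, TGM2, the inhibitor TIMP1 and the ADAM proteases ADAM8, ADAM10, ADAM17 and ADAM19, a wider set than the list's name. Of these 7 rose and 0 fell in sick against healthy pigs (camera adjusted p = 7.6e-07, and adjusted p = 0.0026 with an estimated correlation), and 4 rose and 0 fell in sick against entry pigs (camera adjusted p = 0.0009, and adjusted p = 0.11 with an estimated correlation). Among those higher than in healthy pigs were TGM1, a transglutaminase of skin, at 2.00 ± 0.32 and MMP2, a gelatinase, at 1.70 ± 0.24 on the log2 scale (SE, edgeR adjusted p = 1.3e-05 and 9.1e-07). TIMP1, an inhibitor of metalloproteases, rose by 0.79 ± 0.19 (SE). Against entry pigs TGM1 rose by 1.86 ± 0.36 (SE, adjusted p = 7.8e-05), while MMP2 and TIMP1, at 0.46 ± 0.25 and 0.33 ± 0.2 (SE), were not called (adjusted p = 0.2 and 0.24). MMP2 is also a connective tissue gene and was lower in healthy than in entry pigs, at -1.23 ± 0.25 (SE). Of 17 glycolysis genes 9 rose and 0 fell, including LDHA, the lactate dehydrogenase subunit, at 0.50 ± 0.11 and HK3, a hexokinase of myeloid cells, at 0.72 ± 0.16 (SE); the camera adjusted p was 0.00022, and adjusted p = 0.14 with an estimated correlation. Against entry pigs 5 rose and 1 fell, and glycolysis genes did not pass (camera adjusted p = 0.063). Of 24 lysosome genes 6 rose and 0 fell, with LAMP1, a lysosomal membrane protein, at 0.32 ± 0.093 (SE); the camera adjusted p was 0.00016, and adjusted p = 0.14 with an estimated correlation. Against entry pigs 5 lysosome genes rose and 0 fell (camera adjusted p = 0.0039, and adjusted p = 0.23 with an estimated correlation).

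Of 20 measured cholesterol synthesis genes, 8 fell and 2 rose in sick against healthy pigs, with the enzymes SC5D, FDFT1 and SQLE at -0.48 ± 0.087, -0.41 ± 0.076 and -0.56 ± 0.12 (SE, edgeR adjusted p = 6.8e-05, 0.00011 and 0.00095), while INSIG1, which restrains the pathway, rose by 0.29 ± 0.095 (SE). The camera adjusted p was 0.00016, and adjusted p = 0.14 with an estimated correlation. In sick against entry pigs 9 cholesterol synthesis genes fell and 1 rose (camera adjusted p = 2.3e-05, and adjusted p = 0.14 with an estimated correlation). Of 16 unfolded protein response genes 3 rose and 0 fell, with HSP90B1, a chaperone of the endoplasmic reticulum, at 0.41 ± 0.12 (SE); the camera adjusted p was 0.0036, and adjusted p = 0.3 with an estimated correlation. Against entry pigs 0 rose and 1 fell, and this list did not pass (camera adjusted p = 0.3). Proteasome genes (0 of 18 called), hypoxia and iron genes (2 of 11 called), endothelial genes (2 of 7 called), thymocyte genes (4 of 12 called) and connective tissue genes (1 of 22 called) did not pass as lists in sick against healthy pigs (camera adjusted p = 0.13, 0.75, 0.052, 0.082 and 0.95). The same 7 endothelial genes had a camera adjusted p of 0.047 in the smaller family of lists without genes seen before, and adjusted p = 0.17 with an estimated correlation. In sick against entry pigs 3 of them rose and 0 fell (camera adjusted p = 0.022, and adjusted p = 0.14 with an estimated correlation). In healthy against entry pigs, 15 of 22 connective tissue genes fell, including PI16, a marker of fibroblasts, at -2.61 ± 0.61 (SE). That list was made after its collagens had been seen to fall, and its 7 genes not looked at before, of which 2 fell, did not pass (camera adjusted p = 0.2). Of 18 proteasome genes PSMA5 and PSMD4 fell in that comparison, by -0.29 ± 0.08 and -0.39 ± 0.12 (SE), with a camera adjusted p of 0.00028, and adjusted p = 0.31 with an estimated correlation. In sick against entry pigs 5 proteasome genes fell and 0 rose (camera adjusted p = 2.3e-05, and adjusted p = 0.14 with an estimated correlation).

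Sick pigs differed among themselves in neutrophil markers more than healthy pigs did. The SD of the score was 0.623 in sick and 0.287 in healthy pigs, a ratio of 2.17 (two-sided permutation p = 0.0013 on distances from the group median), or 1.83 without sick 2 and sick 16. The score lay above the highest healthy one in 13 of 23 sick pigs and below the healthy median in 1. IL22RA2 lay above its highest healthy value in 13 of 23 sick pigs, TGM3 in 13, ACVR1B in 13 and MMP8 in 9. The sick group may thus hold pigs in different states, and time since the onset of disease, which would test this, is not given in the sources used here.

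With the neutrophil score in the design, edgeR called 0 genes between sick and healthy pigs, with 1074 at an unadjusted p under 0.05 and a smallest adjusted p of 0.072; limma voom also called 0, with 1153 at an unadjusted p under 0.05. The score itself differed between the groups, which held 41.1% of its variance, so the fit does not part an effect of disease from the share of neutrophils. Among barrows alone 1103 genes were called between sick and healthy pigs and among gilts alone 18. A gap as large as the 1085 between these counts came from 24 of 100 splits with the sexes permuted within groups, with 2227 as the highest other, so the sexes were not shown to differ.

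Other splits of the same libraries into groups of the same sizes made chance unlikely, without excluding it, for the counts of called genes. Of 100 splits each, the real one included, only the real one reached 1805 genes in sick against healthy (highest other 34), 829 in healthy against entry (highest other 15), 2459 in sick against entry (highest other 780) and 27 in gilts against barrows (highest other 2), so 1 split in each. The count for gilts against barrows adds little, since ENSSSCG00000026430 had at least 155 CPM in every barrow and at most 0.475 CPM in every gilt. No other split of the sexes can match that. By genes with an unadjusted p under 0.05, healthy against entry gave 2789, which 2 of 100 splits reached (highest other 2821). For the sex difference in sick against healthy pigs, the real split gave 0 genes, so that all 100 splits reach it whatever the data (highest other 7) and that count tests nothing. Of genes with an unadjusted p under 0.05 the real split gave 647, and 30 of 100 splits gave as many (highest other 2210), so chance was not excluded.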
